A study of Mus musculus with 8 samples.

How the data were processed

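RNA-seq had been run on hearts of male FVB/N mice aged 4 months, with 4 wild-type and 4 AE3-null libraries. AE3, encoded by Slc4a3, is a chloride/bicarbonate exchanger of the heart muscle cell membrane, and AE3-null mice lack the normal gene. The group and the replicate number of each library came from its title and genotype label. The design text speaks of 4 mice of each genotype, and the labels do not otherwise say how the libraries relate to animals, so p-values measure the spread between these libraries.

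The values used are read counts per gene as deposited by the authors, with 1 column per library and no normalization. Per the submitters' processing notes, reads were converted with bcl2fastq from CASAVA 1.8, aligned to mouse genome build mm9 with TopHat, and tested with DESeq. The counting program, its strand setting, the gene annotation and any read filter are not given in the sources used here. Reads of overlapping genes on opposite strands, and of near-identical gene copies, can therefore not be assigned with certainty. The table identifies genes by Entrez number. Of 23282 genes, 23185 were matched to a symbol in an NCBI RefSeq gene table of assembly GRCm38.p6 and 97 were not. Because that assembly is not the build of the files, no coordinates are given, and it was used only for names, for neighbouring genes and for the distances that define windows around Slc4a3.

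Total counts ranged from 9133628 to 27078351 per library. The self-test below gives the size of change that this depth and replication can resolve. A total of 4323 genes had no count in any library. Genes were kept with edgeR's filterByExpr at its default minimum count of 10, which left 14136 genes for testing. Library sizes were scaled by TMM factors, and the genotypes were compared with edgeR's quasi-likelihood F test with robust moderation and no covariates. Positive log2 fold changes mean higher in AE3-null hearts. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Expression levels are given as CPM, counts scaled to a common library total, with the TMM-scaled library sizes, and errors of CPM are standard deviations over 4 libraries.

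Before the data were examined, 17 pathway lists and 13 cell type lists were fixed from general knowledge of the heart. They were tested with limma's camera, two-sided, with the preset correlation of 0.01 between genes, adjusted within each kind of list, and needed at least 3 tested members. Camera with a correlation estimated from the data and limma's fry, which tests whether the genes of a list move one way without comparing them with other genes, were also run. Genes within 10 Mb of Slc4a3 were compared with all other tested genes by a two-sided Fisher's exact test. The rule for genes named in the text was also fixed: Slc4a3, then the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM in a genotype and all 4 libraries of one genotype above all 4 of the other. Predicted or clone-named models and pseudogenes were left out, and a few further genes are not reported here. Up to 4 called members of each list with the smallest p were added, or up to 2 members as values only where a list had none called. Ddx3y and Xist were named to check the sex given in the labels. All other genes named outside this rule were chosen after their values were seen.

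The steps were tested on simulated data. Counts were drawn for the 14136 tested genes from the real means, library sizes and dispersions, with 200 genes changed by known folds. For AE3-null against wild type, edgeR recovered 26 of 49 genes changed 1.25-fold, 41 of 49 changed 1.5-fold and 50 of 50 changed 2-fold. Of its 183 calls, 9 were of unchanged genes. On the same simulated counts, DESeq2 recovered 48 and limma voom 47 of the 50 genes changed 2-fold. A list shifted down 1.15-fold was called by camera and no other list was. The simulated genes varied independently of each other, unlike the members of some lists in the real data (estimated correlation 0.480 for heat shock genes). The simulation therefore cannot show how often camera with its preset correlation calls such lists wrongly.

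Alternatives tried were other size factors (RLE, or total counts only), no filter and a stricter filter, DESeq2, limma voom and edgeR without robust moderation. Others were an adjusted p under 0.1, each library left out and the replicate number as a block. The last left out the 10 most abundant genes or used windows of 5 and 20 Mb. A further 6, chosen after the data were seen, left out genes around Slc4a3 (from the lists also with an estimated correlation), thinned the counts or added a marker score as a covariate. Pairs of libraries of the same genotype differed by a chi-square of 2.59 to 7.75 per gene, so none was a copy of another. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. No column of the table was left out.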

Results

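Gene expression was measured by RNA-seq in whole hearts of wild-type and AE3-null mice. The wild-type libraries held 16159469, 14875281, 15208215 and 19080858 counts in replicates 1 to 4, and the AE3-null libraries 23861125, 9133628, 18774924 and 27078351. The 10 most abundant genes took 13.8% to 14.6% of the counts in each library. All 8 libraries expressed the Y-linked gene Ddx3y at 96.0 to 107 CPM and Xist at no more than 4.43 CPM.

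The first comparison checked the genotype labels. Slc4a3 (Entrez 20536), which encodes the AE3 chloride/bicarbonate exchanger, fell from 383.5 ± 4.60 CPM (SD, n = 4) in wild-type hearts to 32.9 ± 1.26 CPM (SD, n = 4) in AE3-null hearts. The residual level was 8.58% ± 0.330 of the wild-type mean (SD, n = 4). The log2 fold change was -3.54 (SE 0.040, edgeR adjusted p 2.83e-19). Wild-type libraries lay between 378 and 389 CPM and AE3-null libraries between 31.5 and 34.6 CPM, so each library matched its label.

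**Figure D1:**
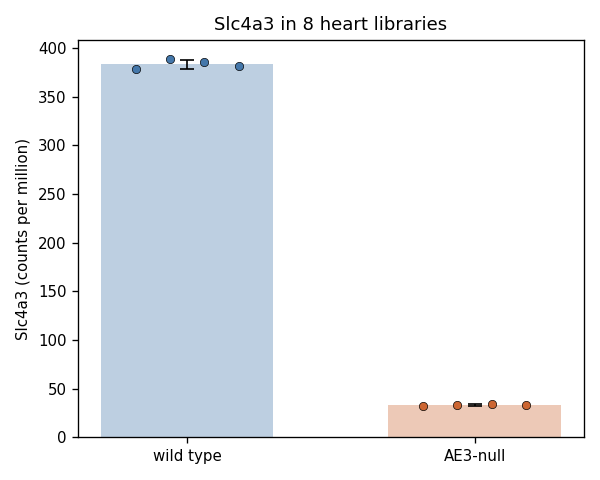
Slc4a3 expression in CPM (vertical axis) in wild-type and AE3-null hearts; bars are means, lines SD and points the 4 libraries of each genotype. The AE3-null libraries lie between 31.5 and 34.6 CPM and the wild-type libraries between 378 and 389 CPM.

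The second comparison asked which genes differ between AE3-null and wild-type hearts. Of the genes named by size, the largest fall was that of Myl1 (Entrez 17901), an essential myosin light chain of atrial and fast skeletal muscle. Myl1 fell from 75.4 ± 4.98 to 16.3 ± 1.5 CPM (SD, n = 4, log2 -2.21, SE 0.069). Acta1, the skeletal actin that fetal and stressed hearts express, fell from 712 ± 196 to 260.4 ± 21.2 CPM (log2 -1.45, SE 0.209). The glutathione-degrading enzyme Chac1 fell by 1.32 on the log2 scale (SE 0.191), the hypoxia-inducible prolyl hydroxylase Egln3 by 0.94 (SE 0.044) and the cytoskeletal adaptor Obsl1 by 0.94 (SE 0.035). Klhl34 fell from 17.4 ± 4.31 to 8.88 ± 1.59 CPM (SD, n = 4). On the log2 scale Ano5, a gene of inherited muscle disease, fell by 0.98, Pacsin1 by 0.91, the Z-disc protein gene Myot by 0.91 and Cnksr1 by 0.88.

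Among the genes named by size, the largest rise was that of Snai3, from 4.01 ± 1.12 to 8.21 ± 0.486 CPM (SD, n = 4; log2 1.03, SE 0.148), and Tlcd4 and Cpne5 rose by log2 1.03 and 1.02. The synaptic vesicle protein gene Sv2a and the transferrin receptor Tfrc each rose by log2 0.95. The angiotensin II receptor Agtr1a rose from 21.5 ± 3.56 to 37.8 ± 1.47 CPM (log2 0.82, SE 0.089). Dbh, the noradrenaline-synthesizing enzyme, rose by log2 0.82, the MHC class II chain H2-Eb1 by 0.81, Plekhh1 by 0.80 and Cep128 by 0.79. The naming rule required that all 20 of these genes have the 4 libraries of one genotype above the 4 of the other. H2-Eb1 belongs to a family whose members share sequence, so its count is uncertain. The calls of Tfrc and Klhl34 had adjusted p-values of 0.0459 and 0.0337, which reached 0.129 and 0.128 in the least favourable of the alternatives chosen beforehand.

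**Figure D2:**
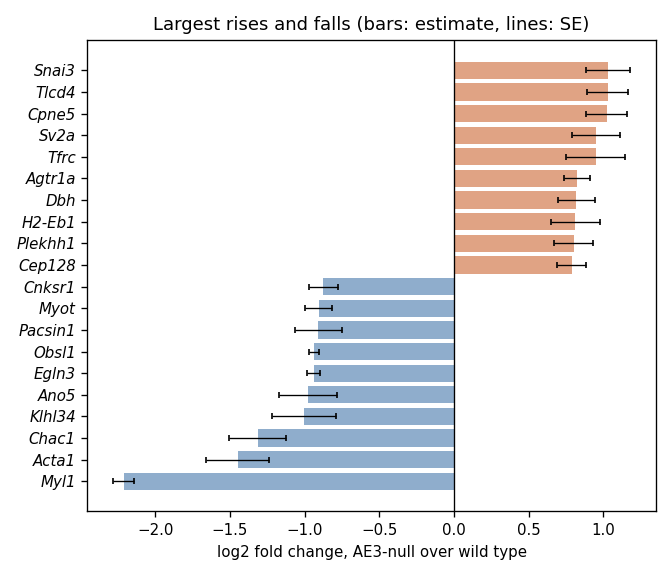
Log2 fold changes, AE3-null over wild type (horizontal axis), of the 10 genes named for the largest rise and the 10 named for the largest fall; bars are edgeR estimates and lines are SE. The falls reach -2.21 for Myl1 and the rises 1.03 for Snai3.

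In all, 915 of 14136 tested genes were called, 447 higher and 468 lower in AE3-null hearts. Most changes were small: the median size of the log2 fold change of called genes was 0.30, 140 called genes changed at least 1.5-fold and 36 at least 2-fold. Of the 140 genes 71 rose and 69 fell. Of all tested genes, 1731 (12.2%) had the genotypes fully separated, against 2.86% by chance. With scaling by total counts only, 528 genes were higher and 361 lower. Leaving out single libraries gave between 407 calls, without AE3-null replicate 4, and 1727, without wild-type replicate 3; 431, 581 and 569 were called without wild-type replicate 4, AE3-null replicate 1 and AE3-null replicate 3, and the lower genes numbered 300 without wild-type replicate 2. Wild-type replicate 3 stood apart on the second principal component (15.7% of the variance), at -22.6 against -1.48 to 8.89 in the other libraries.

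Most genes of the atrial cardiomyocyte list were higher in AE3-null hearts. Of 9 members, 7 rose, 1 (Myl1) fell and 1 (Bmp10, log2 -0.05, SE 0.120) was not called, with the same counts adjusted over the list alone. The atrial light chain genes Myl7 and Myl4 rose from 278 ± 14.0 to 384 ± 29.1 CPM (SD, n = 4; log2 0.47, SE 0.052) and from 454 ± 19.1 to 598 ± 43.4 CPM (log2 0.40, SE 0.048), and Mybphl rose by log2 0.42. The median member rose by log2 0.31, while the mean was 0.03 because of Myl1. Camera placed the list up with an adjusted p of 0.0287, and the adjusted p was 0.525 with an estimated correlation. Without Myl1, an alternative chosen after the data were seen, the adjusted p was 1.37e-13, and 0.107 with an estimated correlation. With all members its call was lost without wild-type replicate 1 (0.151), wild-type replicate 3 (0.210) or AE3-null replicate 3 (0.141), by fry (0.186) and with the replicate number as a block (0.245).

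Cardiac ion channel and gap junction genes were also higher, with 13 of 40 tested members risen and 1 fallen (17 and 3 adjusted over the list alone). Kcnj5, a subunit of the acetylcholine-gated potassium channel, rose from 119 ± 7.44 to 167 ± 9.99 CPM (SD, n = 4; log2 0.50, SE 0.050). The gap junction gene Gja5, expressed in atria and the conduction system, rose by log2 0.58. The potassium channel Kcna4 rose by 1.10, from a low mean of 1.05 to 2.24 CPM, and the T-type calcium channel Cacna1g by 0.28. The list was called up (camera adjusted p 0.000102), with an adjusted p of 0.335 with an estimated correlation. The levels of the atrial markers were higher too: the mean log2 CPM of 8 atrial markers was 7.63 ± 0.0772 in wild-type and 7.93 ± 0.0882 in AE3-null libraries (SD, n = 4).

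Sarcomere genes went both ways. Of 39 tested members 6 rose and 4 fell (6 and 6 adjusted over the list alone), and camera did not call the list (adjusted p 0.802). The risen members with the smallest p were the atrial genes Myl7, Mybphl and Myl4, and Myot fell. Among 33 calcium handling genes 5 rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p 0.920). Phospholamban, Pln, the inhibitor of the sarcoplasmic reticulum calcium pump, rose from 5421 ± 123 to 5972 ± 144 CPM (SD, n = 4; log2 0.14, SE 0.030), sarcolipin, Sln, rose by log2 0.31, Camk2g rose by 0.26 and Camk2b fell by 0.45.

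Endothelial and angiogenesis genes were lower in AE3-null hearts. All 12 endothelial markers had negative log2 fold changes, between -0.49 and -0.08, and 5 fell (7 adjusted over the list alone). Pecam1 fell from 228 ± 9.01 to 190.4 ± 9.87 CPM (SD, n = 4; log2 -0.26, SE 0.043), Kdr, a VEGF receptor, by 0.39, Eng by 0.24 and Esam by 0.20. The call of Kdr was lost in 6 of 18 alternatives chosen beforehand. Of 37 angiogenesis genes 10 fell and none rose (13 fell and 1 rose adjusted over the list alone), with 5 members in both lists. Notch4 fell by 0.36, Vegfa by 0.34, Nrp2 by 0.26 and Notch1 by 0.24. Camera called both lists down (adjusted p 2.63e-07 for endothelial markers and 7.15e-07 for angiogenesis). With an estimated correlation the adjusted p was 0.107 for endothelial markers and 0.0468 for angiogenesis, the only pathway list that stayed called. Red blood cell markers were also lower: their mean log2 CPM was 6.88 ± 0.291 in wild-type and 6.34 ± 0.206 in AE3-null libraries (SD, n = 4).

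The extracellular matrix and hypoxia lists were lower too. Of 39 matrix genes 8 fell and 1 rose (16 and 2 adjusted over the list alone). The basement membrane collagens Col4a1 and Col4a2 fell by 0.37 and 0.33 on the log2 scale, the protease Mmp9 by 0.73 and Thbs4 by 0.37. The list's camera adjusted p was 1.64e-05, and its adjusted p was 0.198 with an estimated correlation. Of 30 hypoxia-response genes 6 fell and 2 rose (11 and 4 adjusted over the list alone), with falls of 0.94 for Egln3, 0.50 for the mitophagy receptor Bnip3, 0.39 for the collagen prolyl hydroxylase P4ha2 and 0.34 for Vegfa. Tfrc, a member of this list, rose. The camera adjusted p was 0.00466, and the adjusted p was 0.352 with an estimated correlation.

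Heat shock and unfolded protein response genes had a median log2 fold change of -0.22 and a mean of -0.35. Of 33 members 6 fell and none rose (14 fell adjusted over the list alone). The small heat shock protein gene Hspb6 fell from 835 ± 53.4 to 709 ± 13.2 CPM (SD, n = 4; log2 -0.23, SE 0.041), Hyou1 by 0.27, Pdia3 by 0.21 and Atf6 by 0.16. The calls of Hyou1 and Atf6 were each lost in 7 of 18 alternatives chosen beforehand. The mean log2 CPM of the heat shock and immediate early lists was 5.52 in wild-type replicate 3, against 5.92 to 6.06 in the other wild-type libraries and 5.52 to 5.76 in AE3-null libraries. Without wild-type replicate 3, 16 of the 33 heat shock genes fell and none rose, with a median of -0.26. The camera adjusted p was 6.84e-09, and the adjusted p was 0.401 with an estimated correlation, since the members vary together between libraries (estimated correlation 0.480). Of 29 immediate early genes 2 fell, Maff by 0.55 and Ppp1r15a by 0.24 (2 adjusted over the list alone), with adjusted p-values of 0.00466 by camera and 0.580 with an estimated correlation. Of 23 hypertrophy markers 4 rose and 3 fell (4 and 6 adjusted over the list alone): Nppa, the atrial natriuretic peptide gene, rose by log2 0.42 and Mef2c by 0.15, whereas Acta1 fell by 1.45 and Fhl2 by 0.21. Camera called this list down (adjusted p 0.00514), and the adjusted p was 0.569 with an estimated correlation and 0.108 without wild-type replicate 2. The median log2 fold change of its members was -0.11, the mean -0.26 and the lowest -1.745. Without wild-type replicate 3, 8 hypertrophy markers fell and 4 rose.

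**Figure D3:**
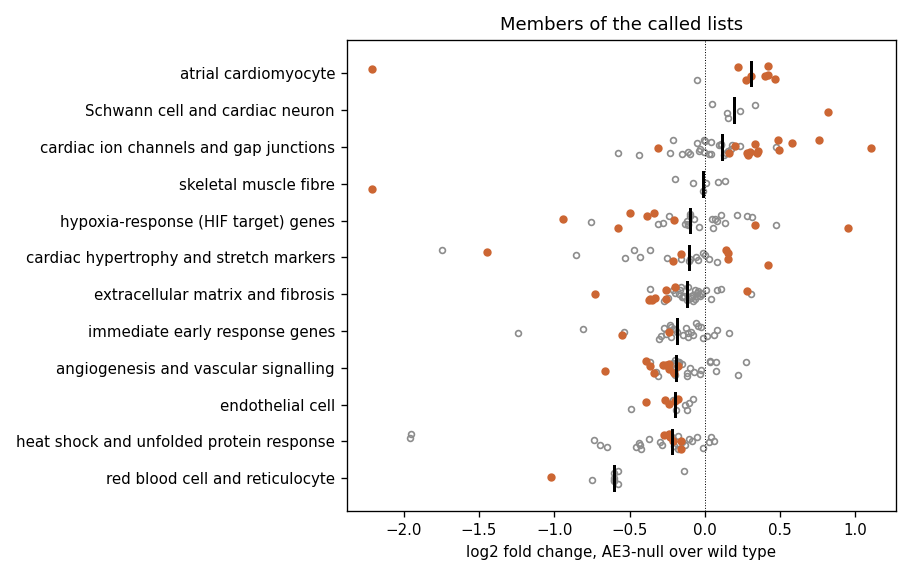
Log2 fold changes, AE3-null over wild type (horizontal axis), of the tested members of each list called by camera; filled points are called genes, open points are not called, and the vertical bar is the list's median. Median values run from -0.60 for red blood cell genes to 0.31 for atrial genes.

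The remaining pathway lists were not called by camera. Of 26 acid-base transporters other than Slc4a3, 2 rose and 1 fell (2 and 2 adjusted over the list alone; camera adjusted p 0.836): the bicarbonate cotransporter Slc4a4 fell by 0.32 on the log2 scale, the anion exchanger Slc26a6 rose by 0.35 and the monocarboxylate transporter Slc16a7 by 0.39. None of 11 carbonic anhydrases was called by edgeR (none adjusted over the list alone; camera adjusted p 0.226). Limma's fry, which does not compare a list with other genes, called this list up (adjusted p 0.00604). The smallest p-values were those of Car5b (log2 0.67, adjusted p 0.0690) and Car14 (log2 0.17, adjusted p 0.162). Car5b was called without wild-type replicate 1 (log2 0.92, edgeR adjusted p 0.0179). Among 43 fatty acid genes 1 rose, Acsl1 (log2 0.16), and 4 fell, among them Ucp2 (by 0.30), Ppard (by 0.29) and Acadl (by 0.14), with 1 and 6 adjusted over the list alone and a camera adjusted p of 0.706. Among 45 glucose genes 1 rose, Hk1 (log2 0.21), and 3 fell, Pfkfb2 by 0.39, Pgam1 by 0.29 and Pfkl by 0.14 (3 and 5 adjusted over the list alone; camera adjusted p 0.234). The call of Pgam1 was lost in 10 of 18 alternatives chosen beforehand, other scalings among them, and that of Pfkl in 6. None of 52 respiratory chain genes was called (none adjusted over the list alone; camera adjusted p 0.802), and Ndufs7 and Ndufs8 were the nearest, at log2 -0.12 and -0.12.

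Of 40 insulin, AKT and mTOR genes 1 rose, Igfbp3 (log2 0.25), and 4 fell, Irs1 by 0.29, Foxo1 by 0.16, Fbxo32 by 0.15 and 1 other (1 and 7 adjusted over the list alone; camera adjusted p 0.451). The calls of Foxo1 and Fbxo32 were lost in 12 and 8 of the 18 alternatives. Of 36 adrenergic and vascular tone genes 4 rose and 3 fell (6 and 4 adjusted over the list alone; camera adjusted p 0.451): Agtr1a, the adrenergic receptor Adra1b (log2 0.48) and the muscarinic receptor Chrm2 (log2 0.27) rose, and the adenosine receptor Adora2a fell by 0.54. No circadian gene was called among 19 (none adjusted over the list alone; camera adjusted p 0.861); Nfil3 and Hlf had log2 fold changes of -0.50 and 0.38. In total camera called 7 of 17 pathway lists, 1 up and 6 down, and with an estimated correlation 1; 6 of the 35 splits of the 8 libraries into 4 and 4, the real one included, gave at least 7 with the preset correlation.

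Among the other cell type lists, red blood cell genes were lower, with a median log2 fold change of -0.60 over 9 members. Over all genes 1 member fell, and 8 fell adjusted over the list alone. Alas2, the heme synthesis enzyme of red cell precursors, had a log2 fold change of -0.60 (adjusted p 0.0583) and the beta globin gene Hbb-bs -0.60 (adjusted p 0.0992). The Hba-a1 and Hba-a2 rows held the same values, and those of Hbb-b1 and Hbb-b2 differed little, so these are fewer measurements than genes. Camera called the list down (adjusted p 3.88e-09; adjusted p 0.151 with an estimated correlation). Schwann cell and neuronal genes were called up (adjusted p 0.0142; 0.151 with an estimated correlation), with Dbh the only called member of 6 (1 adjusted over the list alone). The skeletal muscle list was called down (adjusted p 2.63e-07; 0.0315 with an estimated correlation), but Myl1 was its only called member of 7 (1 adjusted over the list alone), the median was -0.01, and without Myl1 the adjusted p was 0.984.

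Fibroblast, smooth muscle and pericyte, macrophage, adipocyte and epicardial lists were not called (camera adjusted p 0.306, 0.0850, 0.846, 0.778 and 0.215). The smooth muscle and pericyte list was called up without wild-type replicate 4 (adjusted p 0.0334) or AE3-null replicate 1 (0.0188). In the fibroblast list 3 of 12 members fell, Pi16 by 0.31, Mfap5 by 0.25 and Dpt by 0.14 (3 down and 1 up adjusted over the list alone); the calls of Dpt and Mfap5 were lost in 9 and 8 of the 18 alternatives. In the smooth muscle and pericyte list Myh11 rose by log2 0.32 and Abcc9 by 0.16, 2 of 11 members (2 adjusted over the list alone), and Gpm6a rose by log2 0.33 as the only called epicardial marker of 9 (2 adjusted over the list alone). No macrophage marker of 13 and no adipocyte marker of 9 was called, over all genes or adjusted over the list alone, the nearest being Cx3cr1 (log2 0.71, adjusted p 0.109), Cd163 (log2 -0.36), Cfd (log2 -0.24) and Pck1 (log2 -0.85). With single libraries left out Pck1 ranged from -1.39 without AE3-null replicate 3 to -0.47 without AE3-null replicate 4, Cfd ranged from -0.38 without wild-type replicate 3 to -0.09 without wild-type replicate 4, and Cd163 was called without AE3-null replicate 1 (log2 -0.51, edgeR adjusted p 0.0259). Cx3cr1 was called by DESeq2 (adjusted p 0.00388). Too few members passed the filter for a test of the neutrophil (2), lymphocyte (2) and lung (1) lists, and none of these was called: Lcn2 had a log2 fold change of -0.61, Csf3r -0.37, Ptprc 0.12, Cd4 0.11 and Lamp3 -0.06. Each of these values moved by over 1.5 times with 1 library left out. Lcn2 was -0.36 without wild-type replicate 2 and Cd4 0.04 without AE3-null replicate 1. Without wild-type replicate 1 Csf3r was -0.20, Ptprc 0.21 and Lamp3 -0.0045. In the other direction Ptprc was 0.03 without wild-type replicate 3, Cd4 0.17 without wild-type replicate 2 and Lamp3 -0.09 without AE3-null replicate 4. In total camera called 5 of 10 tested cell type lists, 2 up and 3 down, and with an estimated correlation 1; 7 of the 35 splits, the real one included, gave at least 5 with the preset correlation.

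The last comparison asked whether called genes gather around the targeted gene. Within 10 Mb of Slc4a3, by positions in GRCm38.p6, 13 of 85 tested genes were called (15.3%), against 901 of 14050 elsewhere (6.41%), an odds ratio of 2.63 (95% interval 1.33 to 4.82; two-sided Fisher's exact test, p 0.00306). From 1 to 10 Mb 6 of 55 were called, an odds ratio of 1.79 (95% interval 0.624 to 4.19; exact p 0.166). Of the 13 called genes 11 were lower, among them Myl1, Obsl1, Acadl and Irs1. Within 1 Mb 7 of 30 were called, all lower: Obsl1, Inha, Prkag3, Chpf, Stk11ip, Retreg2 and Des, the list of 7 being chosen after their values were seen. Inha fell by 0.78 and Chpf by 0.45 on the log2 scale. Obsl1 fell from 189 ± 2.08 to 98.9 ± 2.70 CPM (SD, n = 4). The odds ratio for the 10 Mb window was 1.70 without wild-type replicate 3 (exact p 0.0647) and 2.11 without AE3-null replicate 1 (exact p 0.0878). Fisher's test treats genes as independent, which neighbours were not: beyond 20 Mb from Slc4a3, 67 pairs of adjacent tested genes were called in the same direction, against a mean of 28.1 in 10000 shuffles (permutation p 1e-04, the smallest they can give; a test chosen after the data were seen).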

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

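In 8 of 194 groups of 4 libraries examined (96 named genes and the total counts, in each genotype) a single library stood far from the other 3. Chance flags about 1 in 20 groups. The gap of the outlying library to its nearest neighbour, as a share of the range of its group, was 0.971 for Pacsin1 and 0.950 for P4ha2, both high in AE3-null replicate 2, 0.874 for Ppp1r15a, also high there, and 0.846 for Gja5, low there. AE3-null replicate 2 had the fewest counts, 9133628. In wild-type replicate 3 Agtr1a (0.857) and Igfbp3 (0.885) were high, and in wild-type replicate 1 Ano5 (0.873) and Mybphl (0.864) were low. Agtr1a stood at 26.8 CPM in wild-type replicate 3 against at most 20.2 in the other wild-type libraries, still below every AE3-null library. Ano5 stood at 4.39 CPM in wild-type replicate 1 against at least 7.94 in the others.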

How the results depend on the processing

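The alternatives with marker scores, thinned counts or genes near Slc4a3 left out were chosen after the data were seen. Slc4a3 stayed called in all alternatives, at a log2 fold change between -3.66 and -3.52. The count of 915 called genes lay between 844 and 973 under the other normalizations, filters and tests and without abundant genes, rose to 1546 (731 higher, 815 lower) at an adjusted p under 0.1, and fell to 634 with counts thinned to the smallest library, which shows what depth limits. Leaving out single libraries gave 407 to 1727 called genes, 214 to 821 higher and 193 to 906 lower; no called named gene changed sign in an alternative chosen beforehand, and 50 of 78 stayed called in all of those. Of the 18 such alternatives, 12 ended the call of Foxo1, 10 that of Pgam1, 9 those of Dpt and Tfrc, 8 those of Fbxo32, Klhl34 and Mfap5, 7 those of Atf6 and Hyou1, 6 those of Hk1, Kdr, Maff, Mef2c and Pfkl, and 5 or fewer those of the other genes that lost it. Named genes without a call gained one in places: Car5b without wild-type replicate 1, Ndufs7 and Hlf without wild-type replicate 3, Cd163 without AE3-null replicate 1, Cx3cr1 by DESeq2, without robust moderation and on thinned counts, Hbb-bs by DESeq2, by voom and without robust moderation, and Alas2 in these 3 settings, without wild-type replicate 2 or AE3-null replicate 4 and on thinned counts. The smooth muscle and pericyte list had an adjusted p of 0.0188 to 0.186 over left-out libraries, 0.0258 on thinned counts and 0.0287 with the red blood cell score. Without wild-type replicate 3 the counts of several lists moved by over 1.5 times: 4 ion channel, 6 glucose, 6 adrenergic and 2 acid-base genes fell, 3 matrix, 4 fatty acid, 2 glucose, 3 insulin and AKT and 3 fibroblast genes rose, 1 angiogenesis gene and 1 carbonic anhydrase rose, 1 circadian and 1 respiratory chain gene rose, and 2 and 1 fell. The near-Slc4a3 odds ratio ranged from 1.70 to 3.56 over left-out libraries, the Slc4a3 log2 fold change from -3.57 to -3.52, the pathway list count from 6 to 7 and the cell type list count from 4 to 6. Over left-out libraries the adjusted p ranged from 0.000368 to 0.0277 for hypoxia, 4.45e-08 to 5.00e-06 for angiogenesis, 2.46e-06 to 0.000800 for ion channels, 3.24e-06 to 0.108 for hypertrophy, 2.02e-06 to 0.000445 for matrix, 1.79e-05 to 0.0485 for immediate early genes, 1.49e-18 to 2.25e-06 for heat shock genes, 0.00648 to 0.210 for atrial, 2.88e-08 to 3.19e-06 for endothelial, 8.78e-19 to 6.57e-07 for red blood cell, 1.88e-08 to 7.48e-05 for skeletal muscle and 0.00373 to 0.0470 for Schwann cell genes.

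With the replicate block 1002 genes were called, 485 higher and 517 lower, and the atrial list had an adjusted p of 0.245. Same-numbered libraries correlated between -0.0397 and 0.162, with 1 of 4 pairs above 0.1 and 2 of 8 libraries closest to their own number. Pairing by number was therefore not detected, and 4 pairs are too few to rule it out. No other list call and no count changed by more than 1.5 times under the block; the calls of Tfrc, Klhl34, Foxo1, Dpt and Mfap5 were lost, and Cx3cr1 was called.

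With an estimated correlation camera called 1 pathway list and 1 cell type list. The adjusted p was 0.352 for hypoxia, 0.335 for ion channels, 0.569 for hypertrophy, 0.198 for matrix, 0.580 for immediate early, 0.401 for heat shock, 0.525 for atrial, 0.107 for endothelial, 0.151 for red blood cell and 0.151 for Schwann cell genes. By fry it was 0.218 for hypertrophy, 0.262 for immediate early, 0.110 for heat shock and 0.186 for atrial genes, and fry called carbonic anhydrases up (0.00604). Camera's preset correlation lies below the estimated one for these lists except carbonic anhydrases (-0.0794). The angiogenesis list had an estimated correlation of 0.0177, close to the preset 0.01, yet its adjusted p rose from 7.15e-07 to 0.0468. A higher correlation is therefore not the only thing that raises p-values under the estimated setting. Without its member near Slc4a3 the skeletal muscle list turned up with an adjusted p of 0.984, and the atrial list had 1.37e-13. With members near Slc4a3 left out and an estimated correlation, camera called 1 pathway list and 0 cell type lists, and the adjusted p was 0.107 for atrial, 0.988 (up) for skeletal muscle, 0.270 for ion channel and 0.217 for matrix genes.

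With the red blood cell score as a covariate 15 genes were called (5 higher, 10 lower), and with the atrial score 18 (5 higher, 13 lower). These scores follow genotype (R squared 0.612 and 0.819), the median standard error of the called genes rose from 0.0635 to 0.101 and 0.149, and their median change from 0.30 to 0.26 and 0.31, so the calls ended mainly through the larger error; with the atrial score 25 of the 915 genes also changed sign, and with the red blood cell score none did. The near-Slc4a3 odds ratio was 69.1 with the red blood cell score and 72.9 with the atrial score. With the red blood cell score the adjusted p was 0.0721 for ion channels, 0.680 for atrial, 0.380 for red blood cell and 0.113 for Schwann cell genes, and circadian (0.0172, down) and macrophage genes (0.0420, up) were called. With the atrial score 3 pathway and 3 cell type lists were called, the adjusted p was 0.0585 for hypoxia, 0.361 for ion channels, 0.0550 for matrix, 0.641 for immediate early, 0.219 for endothelial, 0.272 for red blood cell and 0.447 for Schwann cell genes, the atrial list itself turned down (0.0171), macrophage genes turned up (0.00277), and Hk1 turned to a log2 fold change of -0.0937. The cause of these turns was not tested.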

Other observations

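The gene groups and genes in the first 2 paragraphs, the tests of donor-strain DNA, of adjacent genes and of a common endothelial fall, and the choice of Bmp10 came after the values were seen. A total of 4 such groups were tested, and p-values adjusted over them are by the Benjamini-Hochberg method. The groups were picked from the same calls that the tests count, and no p-value here corrects for that choice. Fisher's test also treats the genes of a group as independent. The p-values therefore describe these groups and are not separate support for them. Genes with symbols that start with H2-, most of them of the major histocompatibility complex, were higher in AE3-null hearts. Of 27 tested, 7 rose and none fell (25.9% against 6.44% of other genes, odds ratio 5.09, two-sided Fisher's exact test, p 0.00131, adjusted p 0.00526), with a median log2 fold change of 0.58. H2-DMb1 rose by log2 0.96, H2-Eb1 by 0.81 and H2-Q2 by 0.69. The mean log2 CPM over the group was 3.95, 3.09, 2.96 and 3.52 in wild-type replicates 1 to 4 and 4.29, 3.85, 3.93 and 3.98 in AE3-null replicates 1 to 4, so wild-type replicate 1 overlapped the AE3-null range. Camera gave p 7.79e-16 with the preset and p 0.0924 with an estimated correlation. These genes share sequence, and H2-Q7 and H2-Q9 held the same values, so single members are uncertain. Of 8 class II genes, 6 of them in this group, 2 rose (Fisher's exact p 0.0903, adjusted p 0.0903).

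Of 25 histone genes, chosen by symbol, 5 fell and none rose, while 6.45% of other genes were called (two-sided Fisher's exact test, p 0.0202, adjusted p 0.0404). H3c14 fell by 0.77 on the log2 scale, H2bc6 by 0.52 and H2bc4 by 0.41. The median log2 fold change was -0.27, and camera gave p 3.72e-05 with the preset and p 0.0200 with an estimated correlation (adjusted p 0.0800). The 25 include the replacement histone genes H1f0, H1f10, H3f3a and H3f3b, which were not called, with log2 fold changes of 0.15, 0.77, 0.12 and 0.01. H2bc23 and H4bc24 held the same values, so these are fewer measurements than genes. Of 22 genes of the NRF2 antioxidant response 4 fell, Txnrd1 by 0.43, Srxn1 by 0.40, Gclm by 0.30 and Ftl1 by 0.26, while the median was -0.03 and Nqo1 had a log2 fold change of -0.01. Their share of 18.2%, against 6.45% of other genes, gave p 0.0502 (two-sided Fisher's exact test, adjusted p 0.0669), and camera gave p 0.00376 with the preset and p 0.0695 with an estimated correlation. Directions were the same with RLE factors and with total counts only. The genomic span of called higher genes had a median of 46.1 kb, of called lower genes 29.0 kb and of other genes 22.4 kb.

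Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many called genes (915, the highest other 21). The real split thus called more genes than any other, and 1 in 35 is the smallest share that this test can give. Every other split mixes the genotypes, which adds their difference to the spread within groups and lowers its count. The test therefore cannot exclude chance for the gene count. As many called pathway lists (7) came from 6 of the 35 splits, the highest other giving 9, and as many cell type lists (5) from 7 of the 35, the highest other giving 7. The split with 9 pathway lists held the genotypes in equal numbers, so chance is not excluded for the number of pathway lists called with the preset correlation. Splits that keep most libraries of a genotype together still carry part of the genotype difference. The splits with 7 cell type lists were of that kind, so for cell type lists these counts can neither exclude chance nor show it.

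Called genes around Slc4a3 are the first pattern. From 1 to 20 Mb away 11.1% of 189 tested genes were called, and 0.620% of 11767 windows of that size on other chromosomes, each with at least 100 genes, held as large a share (1.33% of 13284 windows with any number of genes). DNA from the strain of the targeted stem cells, carried along with the allele, may account for this. Within 1 Mb the odds ratio was 4.43, 0.591% of 8460 windows held as large a share and all 7 called genes were lower, so an effect of the targeted allele on adjacent genes is open as well. From 1 to 10 Mb 6.50% of 12972 windows held as large a share as that around Slc4a3, no table here holds strain variants, and a response to loss of AE3 was not tested apart from them. At each distance the windows were centred on tested genes and overlap, so the same genes count in many of them. The percentages of windows are therefore not shares of independent regions.

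Higher atrial genes are the second pattern. If AE3-null samples held more atrial tissue, atrial markers would also vary together among hearts of the same genotype. The mean pairwise correlation of 8 atrial markers within genotypes was 0.683, above that of all 10000 random lists matched on expression (median 0.00378), which is consistent with a varying share of atrial tissue. Genes under common control would vary together too, so a change of expression in AE3-null atria stays open. Bmp10, an atrial marker, had a log2 fold change of -0.05 (SE 0.120), and the fall of Myl1, which lies within 10 Mb of Slc4a3, is open to the explanations given for that region.

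Lower endothelial and angiogenesis genes are the third pattern, and a lower share of endothelial cells would lower all 12 markers by a common amount. Their weighted mean was -0.18. Cochran's Q gave p 0.0616 in 100000 random draws that used the degrees of freedom of each error, and 0.0109 by the chi-square approximation. The chi-square version was run first and spoke against a common fall, and the other version and its bounds were chosen after that. Both versions treat the errors of the 12 markers as independent, while the endothelial list had an estimated correlation of 0.214. The answer turns on how the errors are modelled, so a lower share cannot be told apart from separate changes of these genes. A difference in stress response at collection was tested with the mean level of heat shock and immediate early genes as a covariate: the median log2 fold change of the 10 called angiogenesis genes was -0.27 before and -0.24 after, their median standard error was 0.0561 and 0.0648, and 2 of the 10 stayed called. The list stayed called by camera with the preset correlation (adjusted p 7.50e-06), but not with an estimated correlation (0.0670). By the bounds set beforehand, which used the preset setting, this spoke against a stress difference. The list's call turned on the correlation setting and most single calls ended. The test therefore cannot decide whether a stress difference lowered the angiogenesis genes. Over all genes 220 were called with this covariate, against 915 without it, and the score followed genotype with an R squared of 0.385. A fall in expression within endothelial cells of AE3-null hearts was not tested and stays open.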
